A study of Homo sapiens with 16 samples.

How the data were processed

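Chromatin immunoprecipitation with sequencing was carried out for BCL11A and ZBTB7A in 16 libraries, 8 of them ChIP libraries and 8 of them controls. BCL11A was measured in HUDEP-2 cells carrying a tamoxifen-inducible, V5-tagged BCL11A (2 ChIP and 2 control libraries, 24 h at 1e-07 M 4-hydroxytamoxifen; the labels also give an amount in nmol, which cannot be compared without a volume). ZBTB7A was measured in K562 cells (4 ChIP and 4 control libraries) and in HUDEP-2 cells lacking the Gγ-globin gene HBG2, with a wild-type (WT) or a 195C>G γ-globin promoter (1 ChIP and 1 control library each). The sample titles call the controls input, whereas the protocol names a control immunoglobulin, and which applies is not given in the sources used here.

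Reads were trimmed with Trimmomatic 0.3.2 and aligned with Bowtie2 2.2.9 to GRCh38/hg38 per the submitters' processing notes, which also name Bowtie, Picard and bedtools. The authors deposited 4 peak lists, a peak being a stretch of genome with more ChIP than control reads. The BCL11A and K562 lists pool the replicates through the irreproducible discovery rate (IDR), a filter that keeps peaks ranked alike in replicates. The WT and 195C>G lists come from the peak caller SPP in 1 library each. The deposited BCL11A list gives a score per region and no summit. The deposited WT and 195C>G lists give a signal per region, the −log10 of the false discovery rate and a summit. Per the file headers and columns, the deposited K562 list holds no value per region, so its order was used as its rank. This choice was made after seeing the data. In the first decile of that order 79.2% of regions were overlapped by a WT region and in the last decile 53.9%, and across 10211 shared regions the Spearman correlation of the order with the WT rank was 0.417 (regions are not independent replicates).

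The WT and 195C>G lists use a modified chromosome 11, for which the authors deposited an annotation without HBG2. Gene ends after HBG1 most often lay 4928 bp lower than in the RefSeq gene table of GRCh38.p14, exactly so for 302 of 1121 genes. Before HBG1, 49 of 126 genes had identical ends in both. Chromosome 11 positions for the hg38 lists therefore came from the RefSeq table (1247 of 1274 genes matched). Chromosome 11 was left out wherever lists of the 2 builds were overlapped, and no coordinate was converted. All coordinates are 1-based.

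Regions were limited to standard chromosomes and identical regions were counted once. Regions that overlapped without being identical were kept apart, so counts of regions are not counts of separate sites. A region counted as a promoter region when its summit, or its midpoint where no summit is given, lay within 1 kb of the transcription start site (TSS) of a protein-coding (NM) transcript. Shares of promoter regions and of overlapping regions (at least 1 bp) were compared with 1000 random placements within the same chromosomes, which can give no one-sided p-value below 0.001. For reciprocal overlap 100 placements were used, with a smallest possible p-value of 0.0099. Promoter-bound gene sets were compared with a one-sided Fisher's exact test, given as log10 p where the p-value was too small to be written. Shares carry exact Clopper-Pearson 95% intervals. No read counts or depths are given for any library, so the depth is unknown and the precision beyond counting error cannot be stated.

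The WT and 195C>G lists come from single libraries, so that comparison has no p-value. The HBG1 promoter region was set beside the 500 WT regions nearest to it in rank. A WT region was called kept when a 195C>G region overlapped it by at least 1 bp. For the chromosomes, each WT region's expected retention was the mean of its decile of WT rank over all chromosomes, chromosome 19 included, which places the others slightly above their expectation. For gene lists, the share of WT promoter-bound genes also bound in 195C>G was placed among 10000 random draws matched on WT signal decile.

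Occupancy was tested for 13 gene lists fixed before the files were opened: globin genes, erythroid transcription factors, NuRD and other corepressor subunits, fetal globin regulators, heme synthesis and iron, red cell membrane and surface, glycolysis, apoptosis and cell cycle, ribosomal proteins, and markers of megakaryocytes, of myeloid cells, of lymphoid cells, and of hepatocytes and neurons. All 325 listed genes matched the annotation, and 8 belong to more than 1 list. The 52 one-sided Fisher's exact tests (13 lists by 4 peak lists) were adjusted together by Benjamini-Hochberg, with a threshold of 0.05.

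Genes were named by a rule fixed in advance: all globin genes; the 3 strongest promoter-bound genes of each gene list in each peak list; the 10 genes with the strongest promoter regions in each peak list; the 10 genes bound in both the BCL11A and K562 lists with the best sum of ranks; the 10 WT-bound genes of best rank whose region had no 195C>G overlap; and BCL11A, ZBTB7A, LIN28B and HIC2. Where a group of these genes is long, its ranks are given as a range. Some genes that the rule names are not reported here.

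The alternatives tried were promoter windows of 500 bp and 5 kb, the stronger 50% of each list, lists of equal length, reciprocal overlap of at least 50%, summits or midpoints within 250 bp, 200 rank-matched regions, rank-matched promoter regions, and a background of genes bound in at least 1 list. Keeping identical regions, leaving out chromosome 19, rank-matched regions outside promoters, a 5 kb window for overlaps of bound genes, and every use of the K562 order were added after the data were seen. A planned search for motif words was not run, because no genome sequence was among the sources used here.

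The methods were tested on simulated data. A planted overlap of 40.3% among 5000 regions was recovered as 40.3% with 0 wrong calls, and random placement gave 0.265% where 0.263% was computed directly. Promoter assignment gave 0 wrong calls for 500 regions. Among 500 simulated lists of 30 genes with an odds ratio of 4, 97.4% were called at an unadjusted p under 0.05 with a median odds ratio of 4.21, and with an odds ratio of 1 it was 2.60%. In the retention draws, 9.67% of 300 random lists of 24 genes fell outside the 5th to 95th percentile. The 12 overlap counts compared with bedtools 2.31.1 showed 0 differences. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.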

Results

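Binding of BCL11A and ZBTB7A, a pair of zinc-finger proteins that repress the fetal γ-globin genes HBG1 and HBG2, was measured by chromatin immunoprecipitation with sequencing (ChIP-seq), which locates a protein on DNA. The 16 libraries, 8 ChIP and 8 control, came from HUDEP-2, an immortalised line of human erythroid progenitors, and K562, an erythroleukaemia line. BCL11A was measured in HUDEP-2 cells with 2 ChIP and 2 control libraries. ZBTB7A was measured in K562 cells with 4 and 4. HUDEP-2 cells lacking HBG2 gave 1 ZBTB7A ChIP library and 1 control with a WT promoter and the same numbers with the 195C>G promoter. The lists were called over pooled replicates or in 1 library, so no error between replicates can be given, and read depth is unknown. Scores and signals of regions are those of the authors and are compared only within their own list. Ranks follow these values, or the order of the file in K562. The rank of a gene is that of its best promoter region in each list, and these regions need not overlap between lists. Intervals cover counting error only, since regions and genes are not replicates.

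The first comparison asked where each factor was bound. The strongest BCL11A promoter region belonged to DIP2A, a gene of lipid metabolism, with a score of 1845 and rank 2. NFE2, which encodes an erythroid transcription factor, stood at rank 10 (score 1270, chromosome 12, 54295667 to 54296327, hg38), and EPOR, the erythropoietin receptor gene, had a score of 951. In K562 the promoter region of PELP1, which encodes a nuclear receptor coregulator, stood at rank 6. PELP1 had the strongest ZBTB7A promoter region in both HUDEP-2 lists, at rank 4 with a signal of 306 in WT and at rank 3 with a signal of 312 in 195C>G.

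The other BCL11A promoters among the 10 strongest were those of SPRYD7, ACYP1 and ZC2HC1C (which share a region), C11orf21, FADS2, GP1BB and KLHDC8B, with scores from 1452 to 914. In K562 they were FAF2, TRAF4, RTN4, CDC27, ACIN1 and C14orf119 (which share a region), ZNF582 and SRF, at ranks 8 to 21. In WT, ACTR3C and LRRC61 shared the region of rank 9, followed by TPGS1, ZSCAN31, ANKLE1, ASPSCR1, S1PR4 and HERC1 at ranks 10 to 23. In 195C>G, HERC1 stood at rank 19, and SYNGR1, TPGS1, TUBB2A, ACTR3C and LRRC61, and FAF2 at ranks 35 to 44.

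The BCL11A list held 12911 regions, of which 42.2% (95% interval 41.3 to 43.0%) were promoter regions against a mean of 1.84% for random placements. The K562 list held 17331 regions, with 44.2% (43.4 to 44.9%) at promoters against 1.88%. The WT list held 36435 regions, with 36.4% (35.9 to 36.9%) against 1.94%, and the 195C>G list 18784, with 37.2% (36.5 to 37.9%) against 1.81%. The one-sided p-value was 0.001 for each list, the smallest that the 1000 placements can give. Regions had median widths of 370, 349, 644 and 600 bp in the BCL11A, K562, WT and 195C>G lists. At least 1 promoter region was found for 4705 BCL11A, 6389 K562, 8684 WT and 5638 195C>G genes, or 24.4, 33.1, 44.9 and 29.1% of protein-coding genes. With the stronger 50% of each list these counts were 2668 for BCL11A, 4007 for K562, 6344 for WT and 3450 for 195C>G.

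The genes of the factors themselves were examined in every list. BCL11A had a promoter region in the BCL11A list (rank 3995), in WT (rank 9864) and in 195C>G (rank 12851), and none in K562. ZBTB7A had one in all 4 lists, at rank 8529 for BCL11A, 1106 in K562, 670 in WT and 3797 in 195C>G. LIN28B, a fetal-stage RNA-binding protein gene, had a promoter region in K562 (rank 12264) and WT (rank 19456). HIC2, a repressor gene of the fetal stage, had one in K562, at rank 13848.

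The γ-globin promoters were examined because the 195C>G variant lies in that of HBG1. BCL11A had a region at HBG1 on chromosome 11 from 5249965 to 5250334 (hg38), which spans -477 to -108 bp relative to the TSS, with a score of 20.9 and rank 9092 of 12911. At HBG2 its region ran from 5254789 to 5255158 (hg38), or -377 to -8 bp, with a score of 49.5 and rank 3471. HBG1 and HBG2 are near-identical paralogs, so their reads cannot be told apart with certainty. ZBTB7A in K562 had no region within 1 kb of either TSS; the closest in the locus, at rank 15129, lay 1900 bp downstream of the HBG2 TSS. With a 5 kb window this region counted for both genes, and K562 had no other there.

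ZBTB7A in WT cells had 1 region at the HBG1 promoter, from 5249672 to 5250315 on the modified chromosome 11. Its summit lay 137 bp upstream of the TSS and it spanned -458 to 185 bp, which includes the variant position. Its signal was 27.3, its −log10 false discovery rate 3.69 and its rank 16655 of 36435. The 195C>G list had no region within 1 kb of the HBG1 TSS. Of the 500 WT regions nearest in rank to the HBG1 region, 263 (52.6%, 48.1 to 57.1%) were overlapped in 195C>G and 237 were not. Each arm is 1 library and the lists differ in length, so the missing region has no p-value.

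**Figure D1:**
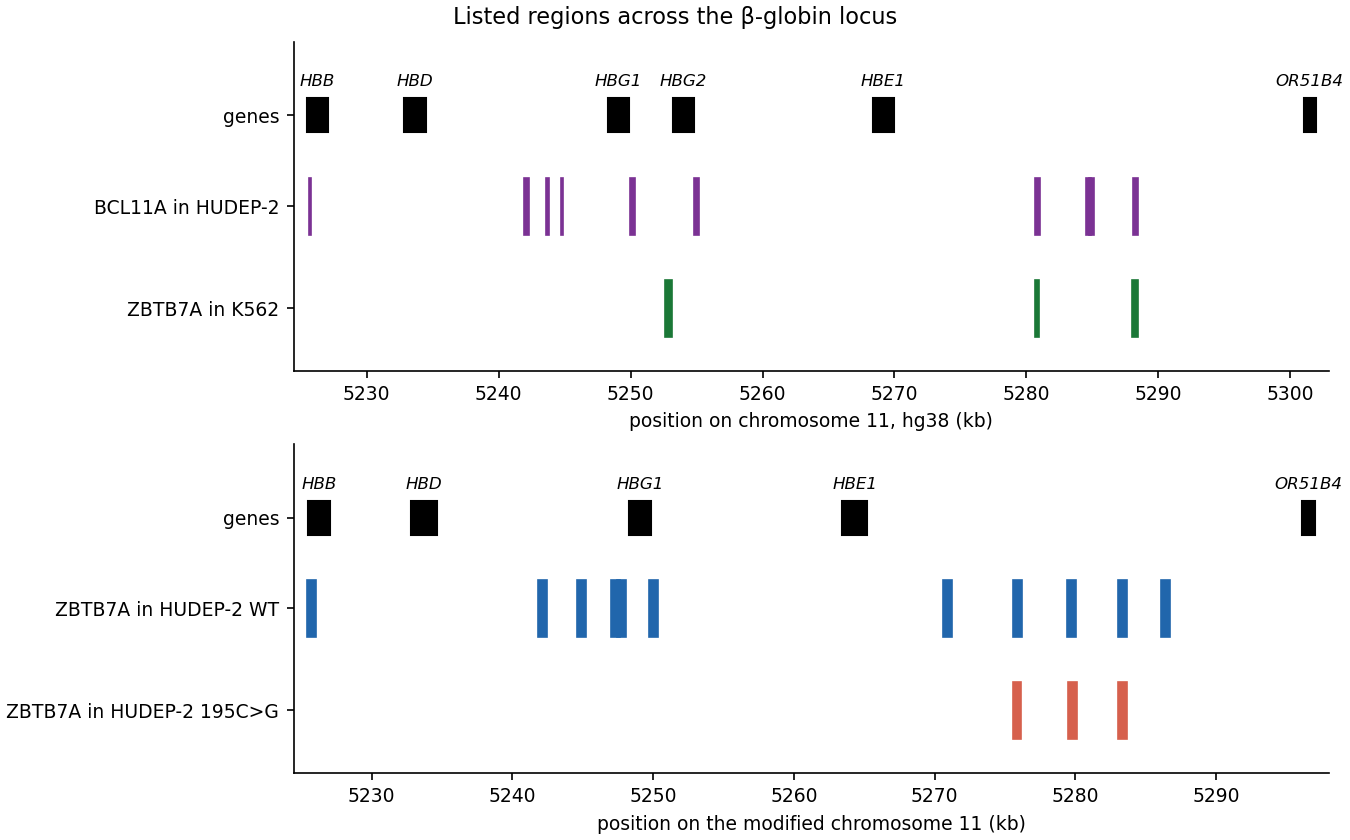
Regions of each list along the β-globin locus, by position on chromosome 11 (hg38 for BCL11A and K562, modified chromosome 11 for WT and 195C>G), with the globin genes. BCL11A has regions at both γ-globin promoters, WT has one at HBG1, and the 3 regions of 195C>G all lie upstream of HBE1.

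The whole β-globin locus, from HBB to OR51B4, was mapped after the values at HBG1 were seen. BCL11A had 10 regions there, 4 of them upstream of the embryonic gene HBE1, where the locus control region lies. The strongest ran from 5280691 to 5281004 (hg38), with a score of 192 and rank 460. K562 had 3 regions, and its best, from 5280690 to 5280992 at rank 2550, lay at the same place. WT had 11 regions, 3 of which were overlapped in 195C>G where their ranks predicted 5.28. Those 3 lay upstream of HBE1, as did all 3 regions of the 195C>G list, at ranks 6741, 7857 and 14284.

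The α-globin locus on chromosome 16 was mapped after the same values were seen. A region in an intron of NPRL3, the gene that carries the α-globin enhancers, stood at rank 16 in WT (113223 to 113903, hg38, signal 257), rank 82 in 195C>G (signal 203) and rank 41 in K562. BCL11A had a region there at rank 2351 and a stronger one from 143034 to 143368 at rank 550, with a score of 174. Of 27 WT regions in the locus, 17 were overlapped in 195C>G, against 17.5 predicted from their ranks. HBM, an α-like globin gene, had a promoter region in WT at rank 456 (signal 130), in 195C>G at rank 4002 and in the BCL11A list at rank 7177. HBQ1, which encodes θ-globin, had one at rank 873 in K562, 869 in WT, 923 in 195C>G and 11170 in the BCL11A list. The embryonic gene HBZ had one in all 4 lists, at rank 1946 for BCL11A, 4925 in K562, 12510 in WT and 5231 in 195C>G. HBA2 had one in the BCL11A list (rank 12733) and HBA1 in WT (rank 19883), and since HBA1 and HBA2 are near-identical, their reads cannot be told apart with certainty. HBB, HBD and HBE1 had no promoter region in any list.

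The overlap of BCL11A in HUDEP-2 with ZBTB7A in K562 asked how often both repressors bound the same places. Genes were ranked by the sum of their promoter regions' ranks in both lists, and the regions themselves need not overlap. The promoter of KMT2B, a histone methyltransferase gene, had the best sum of ranks, 118 for BCL11A and 195 for ZBTB7A. U2AF2, a splicing factor gene, had ranks 226 and 161 in regions that did not overlap, and FAM3C, which encodes a secreted protein, had 177 and 263. PDIA6, a gene of protein folding, had ranks 55 and 402, and a BCL11A score of 582. HNRNPR, DNAJB2, VARS, PDE4C, and HIRA with MRPL40 (which share a region) completed the 10 best, with BCL11A ranks from 117 to 539 and ZBTB7A ranks from 53 to 426.

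Of the 12911 BCL11A regions, 4125 (31.9%, 31.1 to 32.8%) were overlapped by a K562 ZBTB7A region, against a mean of 0.538% for random placements. In the reverse direction 24.1% (23.5 to 24.8%) of K562 regions were overlapped by BCL11A, against 0.406%. Both one-sided p-values were 0.001, the smallest that 1000 placements can give. Overlap was 42.7% for BCL11A promoter regions and 24.1% for those outside promoters, a division added after the data were seen. Promoter-bound genes shared by the lists numbered 2862, against 1556 expected from independent sets (odds ratio 4.88, log10 p of -451, one-sided Fisher's exact test). With reciprocal overlap of at least 50%, the BCL11A share was 18.9% and the K562 share 14.3%, each with a p-value of 0.0099, the smallest for 100 placements. The lists come from different cell lines. Random placement ignores open chromatin and gene density, so these folds do not separate shared targets from shared accessible DNA.

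Within HUDEP-2, an overlap added after the data were seen and without chromosome 11, 57.5% of BCL11A regions were overlapped by a WT ZBTB7A region (random placements 1.43%). By the shorter 195C>G list 39.6% were overlapped (0.684%). Both one-sided p-values were 0.001, the smallest possible. The WT list held 36435 regions covering 19.6 Mb, against 17331 covering 6.15 Mb in K562. For BCL11A regions the fold over random was 40.1 with WT and 59.4 with K562. The higher share within HUDEP-2 therefore does not show more shared binding. Peak calling also differed, and the BCL11A and ZBTB7A libraries came from differently modified HUDEP-2 cells.

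ZBTB7A in K562 and in WT HUDEP-2 cells was compared to see how far its binding was shared between erythroid lines. The promoter of PELP1 stood at rank 6 in K562 and rank 4 in WT. ABCB10, which encodes a mitochondrial transporter of heme synthesis, stood at rank 560 in K562 and 83 in WT, and TFR2, a transferrin receptor gene, at 345 and 103. Without chromosome 11, 62.5% (61.8 to 63.3%) of K562 regions were overlapped in WT against 1.49% for random placements, and 35.9% (35.4 to 36.4%) of WT regions in K562 against 0.765%. Both one-sided p-values were 0.001, the smallest possible. Promoter-bound genes shared by both numbered 4823, against 2734 expected (odds ratio 10.3, log10 p of -997, one-sided Fisher's exact test). With reciprocal overlap of at least 50%, the shares were 35.7% and 18.9% (p of 0.0099 each, the smallest for 100 placements). Cell line and method of peak calling differ together between these lists, so a region found in 1 of them is not shown to be specific to that line.

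The WT and 195C>G lists were compared to see which ZBTB7A regions were found in both. The WT promoter region of best rank without a 195C>G overlap was that of ZNF582, a zinc-finger gene, at rank 398 with a signal of 136. ATP5SL, which encodes a mitochondrial assembly factor, followed at rank 592, AP1M1, a clathrin adaptor gene, at rank 655, and CYP2S1, a cytochrome gene, at rank 820. DMWD, GYS1 and RUVBL2 (which share a region), MED26 and ZNF554 stood at ranks 1006 to 1105. Of the 10 genes under the naming rule, 9 lie on chromosome 19. Among the 1000 WT-bound genes of best rank, 20 had no overlap, 18 of them on chromosome 19, which holds 187 of the 1000.

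Of the 36435 WT regions, 54.3% (53.8 to 54.9%) were overlapped in 195C>G, and of the 18784 195C>G regions 89.3% (88.9 to 89.7%) were overlapped in WT. By WT rank, overlap was 96.0% in the strongest decile, 55.1% in the fifth and 23.8% in the weakest. Promoter-bound genes shared by both numbered 5486, with 3198 found in WT alone and 152 in 195C>G alone. With the stronger 50% of each list the shared genes numbered 3320. Ranks from lists of different lengths show no change in binding, and with 1 library per arm a missing region is not shown to be lost.

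**Figure D2:**
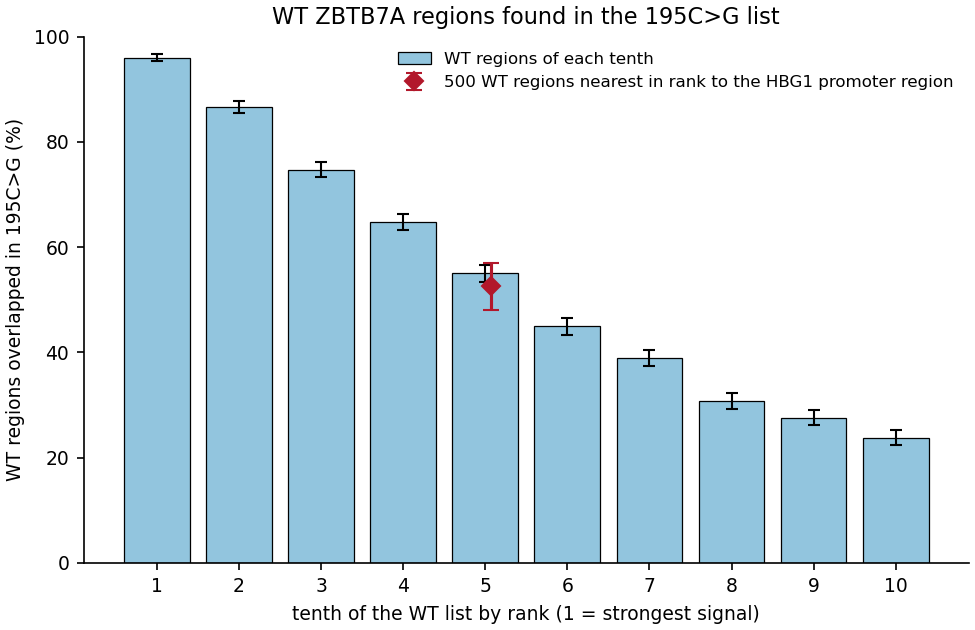
Share of WT ZBTB7A regions overlapped by a 195C>G region (percent) in each decile of WT rank, with exact 95% intervals. The share goes from 96.0% in the strongest decile to 23.8% in the weakest, and the diamond marks the 52.6% of the 500 regions nearest in rank to the HBG1 promoter region.

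On chromosome 19, 40.0% (38.5 to 41.6%) of 3988 WT regions were overlapped in 195C>G, against 58.7% expected from WT regions of similar rank. The difference was -18.7 percentage points, and the other autosomes lay between -3.02 points (chromosome 21) and 5.92 points (chromosome 22). Chromosome 19 held 10.9% of WT, 7.02% of 195C>G, 9.11% of K562 and 9.30% of BCL11A regions. Retention by chromosome was examined after the positions of the missing promoters were seen. Without chromosome 19, 54.8% of the regions matched in rank to HBG1 were overlapped.

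**Figure D3:**
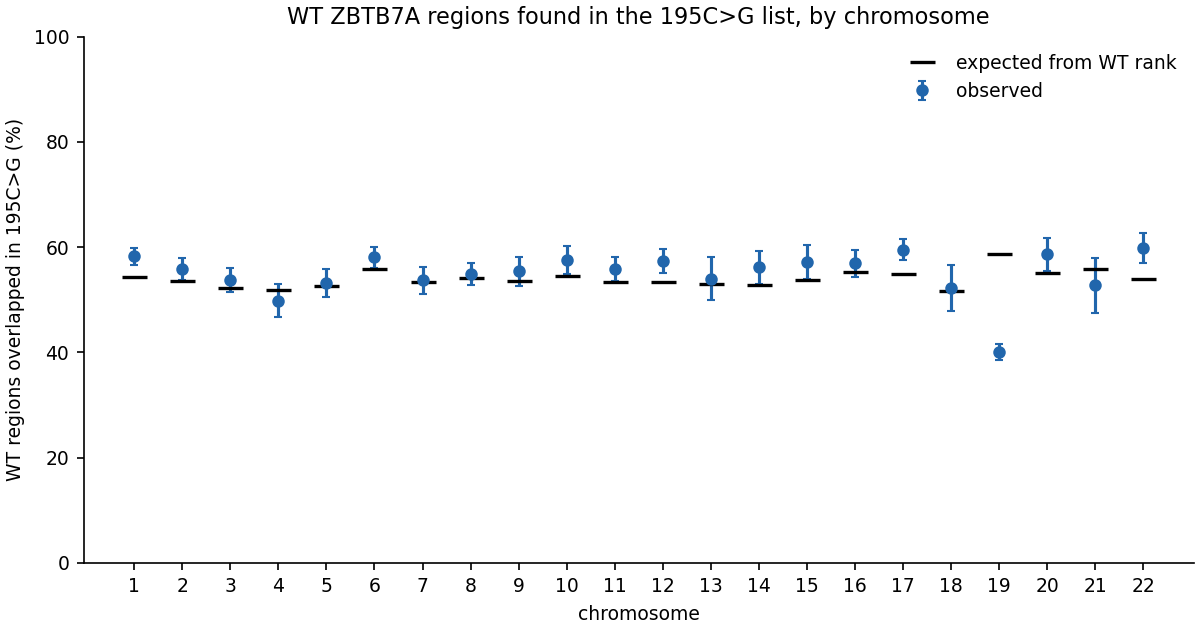
Share of WT ZBTB7A regions overlapped in 195C>G (percent) for each autosome, with exact 95% intervals; dashes mark the share expected from WT rank. Chromosome 19 lies at 40.0% against 58.7% expected.

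The gene lists asked which functional groups were bound at their promoters more often than other genes. The other genes were not matched for expression or open chromatin. A list past the threshold therefore does not separate its function from activity of its genes in these cells. Genes of heme synthesis and iron were bound by BCL11A in 23 of 29 cases (odds ratio 12, adjusted p of 3.79e-08), with FECH, which encodes ferrochelatase, at rank 127, ABCB6 at 1635 and TFR2 at 2077. In K562, 23 of 29 were bound (7.78, 7.32e-06), led by the ferritin gene FTH1 at rank 112. In WT, 22 were bound (3.86, 0.00226), with ABCB10 at rank 83 and TFR2 at 103, and in 195C>G 19 (4.63, 0.00055), with TFR2 at rank 62 and ABCB10 at 129. The other genes of the annotation were bound at about 24.3% by BCL11A, 33.0% in K562, 44.8% in WT and 29.1% in 195C>G.

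Erythroid transcription factors were bound by BCL11A in 17 of 32 cases (odds ratio 3.53, adjusted p of 0.00186). After NFE2, the best were FOXO3 at rank 121 and GATA2, an early progenitor factor, at rank 193. In K562, 26 of 32 were bound (8.80, 7.42e-07), led by TCF3 at rank 103, MYC at 128 and NFE2L2 at 193. In WT, 24 were bound (3.69, 0.00212), with LYL1 at rank 55, the erythroid activator gene KLF1 at 153 and NFE2 at 256. In 195C>G, 18 were bound (3.13, 0.00352), with NFE2 at rank 75, KLF1 at 253 and LYL1 at 430.

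Fetal globin regulators were bound in 13 of 24 cases by BCL11A (odds ratio 3.68, adjusted p of 0.00441), 17 in K562 (4.92, 0.00109), 20 in WT (6.15, 0.000937) and 17 in 195C>G (5.92, 0.000373). With the stronger 50% of the BCL11A list 6 of 24 were bound and that call ended (2.08, 0.214). It also ended against a background of bound genes (1.63, 0.540), and it held with a 5 kb window (5.88, 0.000145). DNMT1, which encodes the maintenance DNA methyltransferase, stood at rank 596 for BCL11A, followed by NR2C2 at 918 and ZNF410 at 1461. In K562 the best were NFIA at 811, ZBTB7A, and KLF1 at 1146. ATF4, a stress-response factor gene, stood at 313 in WT and 165 in 195C>G, beside KLF1 in both, ZBTB7A in WT and SPOP at 2598 in 195C>G. NuRD and other corepressor subunits were bound in 14 of 25 cases by BCL11A (3.96, 0.00226), 15 in K562 (3.04, 0.0121) and 14 in 195C>G (3.1, 0.0111). In WT 16 were bound (2.18), which did not pass the threshold (0.0826) but did with the stronger 50% of the list (15 of 25, 3.08, 0.0139). Against a background of genes bound in at least 1 list the WT direction turned (0.593, 0.988). MTA2, which encodes a NuRD subunit, stood at rank 44 in K562, 504 in WT and 306 in 195C>G, and the deacetylase gene HDAC2 at 2060, 358 and 636. GATAD2A, another subunit gene, stood at 1020 for BCL11A, 1110 in WT and 2405 in 195C>G. Its WT and 195C>G regions did not overlap. The other best-ranked members were DNMT1 and CTBP2 (1090) for BCL11A and MBD3 (1735) in K562.

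Genes of the red cell membrane and surface were bound in 15 of 31 cases by BCL11A (odds ratio 2.92, adjusted p of 0.0081), 19 in K562 (3.21, 0.00352), 24 in WT (4.22, 0.00109) and 19 in 195C>G (3.86, 0.00109). ADD1, which encodes the membrane skeleton protein adducin, stood at rank 320 for BCL11A. The blood group gene KEL stood at rank 224 in K562, ahead of STOM at 906. The ankyrin gene ANK1 stood at 1470 in K562, 140 in WT and 176 in 195C>G. ICAM4 (206) and ACKR1 (423) followed it in WT, and EPB42 (411) and STOM (671) in 195C>G. Genes of apoptosis and cell cycle were bound in 13 of 29 cases by BCL11A (2.53, 0.0266), 20 in K562 (4.51, 0.000712), 22 in WT (3.86, 0.00226) and 18 in 195C>G (3.99, 0.00109). With the stronger 50% of the BCL11A list the direction turned, with 3 of 29 bound (odds ratio 0.720, adjusted p of 1.00). BCL2L1, a survival gene, stood at rank 519 in K562, 347 in WT and 442 in 195C>G, and BBC3, a death-promoting gene, at 763 in K562 and 243 in WT. MDM2, which restrains p53, had ranks 2915 for BCL11A, 1230 in K562, 427 in WT and 811 in 195C>G. CDKN1B (5145) and BCL2L11 (5585) followed for BCL11A, and BNIP3L, a gene of mitochondrial clearance, led in 195C>G at 413.

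The globin genes passed the threshold for BCL11A, with 6 of 10 bound (odds ratio 4.66, adjusted p of 0.0346). With the stronger 50% of the list 2 of 10 were bound and the call ended (1.56, 0.648), as it did against a background of bound genes (7.55, 0.299); over the 4 alternatives the adjusted p ranged from 0.00300 to 0.648. They did not pass in K562 (2 of 10, 1.00), WT (5 of 9, 0.593) or 195C>G (3 of 9, 0.764). Glycolysis genes passed in K562, with 13 of 21 bound (3.29, 0.0142), where ENO1, the enolase gene, stood at rank 1235, HK1 at 2813 and BPGM at 2828. They did not for BCL11A (5, 0.876), WT (11, 0.516) or 195C>G (9, 0.229). HK1, the hexokinase gene, stood at 1162 for BCL11A, 1891 in WT and 3237 in 195C>G. ALDOA (2992) and PFKM (5010) for BCL11A, BPGM (6335) and PKM (6603) in WT, and ENO1 (3114) and ALDOA (4898) in 195C>G completed the best-ranked members. Ribosomal protein genes passed in WT, with 35 of 58 bound (1.87, 0.0266), and not for BCL11A (19, 0.173), K562 (22, 0.429) or 195C>G (21, 0.259). RPL13A stood at rank 95 for BCL11A, with RPLP2 at 455 and RPL18 at 908. RPLP0 stood at rank 214 in K562, 513 in WT and 1321 in 195C>G, beside RPS20 (942) in WT and RPS21 (865) in 195C>G. Whether these lists differ between factors or cell lines was not tested.

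Markers of other cell types passed in no list, with adjusted p-values from 0.697 to 1.00. The one-sided Fisher's exact test asks only for more binding, so high p-values do not show equal binding. Odds ratios were below 1 except for megakaryocyte markers with BCL11A (1.24). In WT, 12.5% of hepatocyte and neuron markers were bound against 44.9% of other genes (odds ratio 0.175). Depletion was not tested. Megakaryocyte markers were bound in 4, 3, 3 and 3 of 14 cases by BCL11A, K562, WT and 195C>G. GP1BB, a platelet glycoprotein gene, stood at rank 16 for BCL11A, 12360 in WT and 6885 in 195C>G, and the other best-ranked members were TUBB1, ITGB3, NBEAL2 and ITGA2B, at ranks from 382 (TUBB1, BCL11A) to 34162 (ITGB3, WT). Myeloid markers were bound in 2, 3, 3 and 2 of 18 cases, with SPI1, the gene of a myeloid factor, at rank 8544 for BCL11A, 531 in K562, 844 in WT and 402 in 195C>G. The other best-ranked members were AZU1, CEBPA, LYZ and CSF1R, at ranks from 2494 (AZU1, BCL11A) to 34922 (CSF1R, WT). Lymphoid markers were bound in 1, 3, 4 and 3 of 18 cases, the best-ranked being RAG1, CD79A, CD79B, PAX5 and CD8A, from 4754 (RAG1, K562) to 17601 (CD8A, WT). Hepatocyte and neuron markers were bound in 2, 4, 3 and 3 of 24 cases, the best-ranked being MBP, SYP, GAD1, GRIN1, SYN1 and APOC3, from 1315 (MBP, BCL11A) to 12961 (GRIN1, K562).

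In all, 7 of the 13 lists passed for BCL11A, 7 in K562, 6 in WT and 6 in 195C>G. Against a background of genes bound in at least 1 list, these counts were 1, 1, 0 and 0, with 2, 3, 0 and 1 at an unadjusted one-sided p under 0.05 by Fisher's exact test. This background comes from the same 4 peak lists, the tested one included. About 81.8% of its other genes were bound in WT, which left little room for more binding there. Of the WT lists that had passed, the direction turned for erythroid transcription factors (odds ratio 0.890), heme synthesis and iron (0.699), and apoptosis and cell cycle (0.979). Of those that had not, it turned for corepressor subunits (0.593) and glycolysis (0.612). The lists still past the threshold were heme synthesis and iron for BCL11A (odds ratio 4.83, adjusted p of 0.00664) and erythroid transcription factors in K562 (4.31, 0.0413), which were the highest adjusted p-values of these lists over 4 alternatives. The lowest, with a 5 kb window, were 4.13e-11 and 3.52e-08. With the stronger 50% of its list, BCL11A had 3 lists past the threshold: erythroid transcription factors, heme synthesis and iron, and red cell membrane and surface. Without chromosome 19, fetal globin regulators (odds ratio 2.58, adjusted p of 0.068) and red cell membrane and surface (2.37, 0.0502) no longer passed for BCL11A. Nor did ribosomal proteins in WT (1.71, 0.0828) or corepressor subunits in 195C>G (2.43, 0.068). Fewer genes enter these tests and all 4 odds ratios stayed above 1, so they do not show that chromosome 19 carried the results. Over the 4 alternatives the adjusted p-values of these results ranged from 0.000145 to 0.54, 0.00248 to 0.54, 0.00288 to 0.975 and 0.00752 to 0.634 in the same order. Genes are not replicates, and the p-values describe the lists alone.

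**Figure D4:**
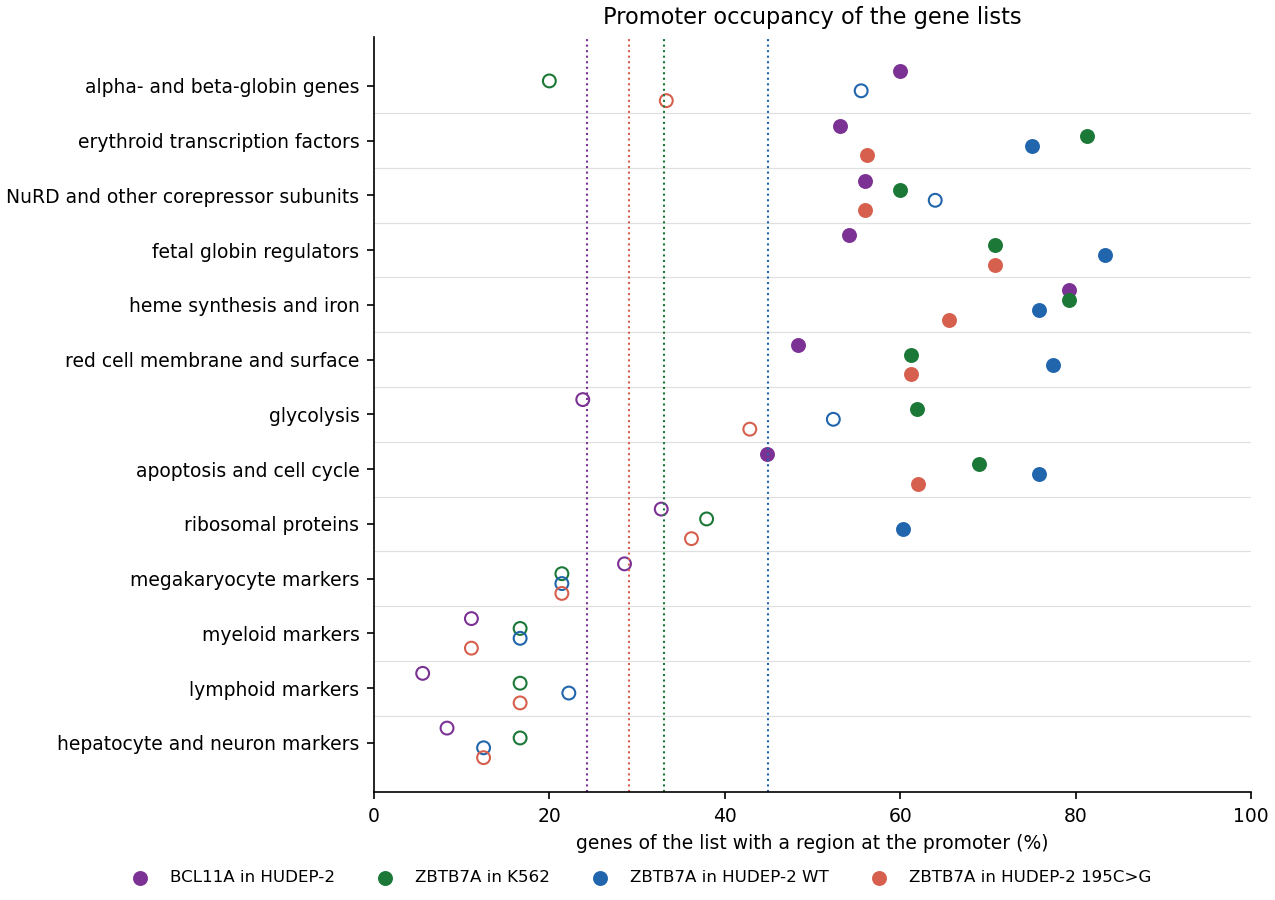
Share of the genes of each list (percent) with a promoter region in each of the 4 peak lists; filled points have an adjusted p under 0.05 (one-sided Fisher's exact test) and each dotted line is the share of all other genes in that peak list. Heme synthesis and iron genes are bound in 23 of 29 cases by BCL11A.

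Retention of gene lists was compared to see whether groups of WT-bound genes were found in 195C>G as often as other genes of like signal. Ribosomal protein genes were kept in 19 of 35 cases (54.3%), against 66.9 ± 6.56% (SD of 10000 draws), at percentile 3.00. Fetal globin regulators were kept in 17 of 20 cases (85.0%), at percentile 93.5, and globin genes in 3 of 5 (60%), at percentile 31.7. Of the 13 lists, ribosomal proteins alone lay outside the 5th to 95th percentile. In the simulated draws, 9.67% of random lists of 24 genes also fell outside these limits. With 13 lists compared, ribosomal proteins are therefore not shown to stand apart from random lists. Without chromosome 19 ribosomal proteins lay at percentile 37.7 (18 of 28 genes). With a 5 kb window they lay at 3.41 and fetal globin regulators at 98.1. The other 10 lists lay between percentile 48.0, for erythroid transcription factors, and 89.5, for glycolysis. Single libraries allow no test of these differences.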

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

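Keeping identical regions, leaving out chromosome 19, rank-matched regions outside promoters, a 5 kb window for overlaps of bound genes, and the K562 order used as its rank were tried only after the results were seen. The other alternatives were set before the data were examined. The overlap within HUDEP-2, the division of overlap by promoter, retention by chromosome and the maps of the globin loci were also added after the data were seen. Over all alternatives, 245 values kept their direction and their side of the threshold, stayed within their spread or, for counts, stayed within a fixed ratio of the main value. A count that kept this label can still have changed. Of the other values, 26 moved, 28 fell short of a threshold they had passed, 1 newly passed it (corepressor subunits in WT with the stronger 50% of the list) and 16 reversed. Fractions at promoters and the overlaps with random placement kept a p-value at the smallest possible in each alternative run. No paired analysis was possible because no label pairs the libraries of the WT and 195C>G arms and each arm holds 1 library. Leaving out replicates was impossible, since the lists are pooled or come from 1 library, and the motif search was not run because no genome was among the sources. Read depth is unknown, so what depth limits could not be judged.

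Taking the stronger 50% of each list lowered promoter-bound genes to 2668 (BCL11A), 4007 (K562), 6344 (WT) and 3450 (195C>G). It lowered genes bound in both WT and 195C>G to 3320, and gene lists past the threshold for BCL11A to 3. Fewer regions enter by construction. Apoptosis and cell cycle genes reversed for BCL11A (odds ratio 0.720). Glycolysis, which had not passed for BCL11A, turned to 1.04 there, 1.05 without chromosome 19 and 1.81 at 5 kb, and globin genes in K562 to 1.58 at 5 kb. For the WT and 195C>G overlap, the shares of WT and of 195C>G regions were 51.6 and 88.0% with the stronger 50%, 44.7 and 77.7% with reciprocal overlap, 49.4 and 85.7% within 250 bp, and 74.7 and 72.9% at equal length. They were 56.1 and 88.8% without chromosome 19, and 54.9% of WT regions with identical regions kept. Stricter overlap and longer or shorter lists change these by construction.

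With a 5 kb window, regions numbered 2 at HBG2 for BCL11A, 1 at HBG1 and 1 at HBG2 in K562 (the same region, between the genes), and 4 at HBG1 in WT, while 195C>G had none at HBG1; 2 lists lay outside the retention percentiles, and without chromosome 19 0 did. Limiting the background to genes bound in at least 1 list left 1, 1, 0 and 0 lists past the threshold for BCL11A, K562, WT and 195C>G. It turned 3 WT results that had passed to odds ratios below 1, erythroid transcription factors (0.890), heme synthesis and iron (0.699), and apoptosis and cell cycle (0.979). Among those that had not, it turned corepressor subunits (0.593) and glycolysis (0.612) in WT, ribosomal proteins (0.727) and hepatocyte and neuron markers (1.32) in K562, and globin genes (0.883), ribosomal proteins (0.883), megakaryocyte markers (1.32) and lymphoid markers (1.32) in 195C>G. This background removes unbound genes from the comparison, which raises the bound share of the other genes. Whether anything else contributes is open, and the cause was not tested.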

Other observations

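The tests on HBG1, on windows of chromosome 19, on gene density, on regions matched in WT rank and on the strongest decile, and the counting spread of the K562 margin, were chosen only after the result was seen. The tests of rank change and of K562 regions were set before their results, though the share of each list on chromosome 19 was already known. The strongest regions outside promoters were also picked after their values were seen. The best BCL11A region lay within ZFPM1, the gene of the GATA1 cofactor FOG1, on chromosome 16 from 88491496 to 88492245 (hg38), with a score of 2348. ZFPM1 held 19 BCL11A regions, and 12, 17 and 13 ZBTB7A regions in K562, WT and 195C>G. The first ZBTB7A region in both K562 (16031172 to 16031751, hg38) and WT (16031123 to 16031792, signal 381) lay on chromosome 6 and stood at rank 7 in 195C>G. Its nearest TSS was that of MYLIP, a ubiquitin ligase gene, with the WT region at -97654 bp. A region on chromosome 8 downstream of MYC (127898480 to 127899324 in 195C>G, 162824 bp from the TSS) had rank 7 in K562, 2 in WT and 1 in 195C>G. A region upstream of LARP1 on chromosome 5 (-58865 bp from the TSS in 195C>G) had ranks 9, 5 and 2. Genes are named here by position and are not shown to be targets.

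A few more of the 10 best HUDEP-2 regions are named for their genes' known roles in red cells, with no test of enrichment, and others of the 10, such as that of PELP1, were left aside. In WT a region in ANK1 (41772581 to 41773247 on chromosome 8) had rank 3 and one in LDB1, which encodes a looping cofactor, rank 8. In 195C>G a region upstream of the iron importer gene SLC25A37 (-34500 bp from the TSS) had rank 4. One in AHI1, the neighbour of MYB, had rank 8, and one in CCND3, a cyclin gene of red cell maturation, rank 9. The BCL11A gene held 6 regions in WT, 5 in 195C>G, 1 in the BCL11A list and 0 in K562.

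The HBG1 promoter region was listed in WT and not in 195C>G. Of the WT regions nearest to it in rank, 47.4% were missing too, so absence from the 195C>G list was common at this rank. List length alone is not shown to explain it, since rank 16655 lies within the 18784 regions of 195C>G. With both lists at equal length, only the WT list was shortened, and 74.7% of its 18784 strongest regions were overlapped. The 500 regions nearest to HBG1, at WT ranks 16405 to 16905, all stay in that cut, and their share is unchanged at 52.6%. The difference in length is thus not needed for the missing ones. Why regions rank differently in 2 single libraries was not tested. Fewer regions over the whole β-globin cluster could not be decided: 3 of 10 other regions were kept where 4.76 were expected (one-sided exact probability 0.187). An effect of the 195C>G variant on ZBTB7A binding, the biological difference of the design, stays open as untested, since each arm is 1 library.

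Regions of chromosome 19 were kept less often in 195C>G than their ranks predicted. All 25 windows of 2 Mb with at least 20 regions lay below expectation, which a difference over the whole chromosome, such as in copy number, would also give. The deficit was uneven. It was -10.2 points in the window at 32 Mb (55 regions), -40.9 at 56 Mb (48 regions) and -40.8 at 58 Mb (60 regions). The count of windows therefore does not show an even difference along the chromosome. Over the other 21 autosomes, with expectations computed without chromosome 19, denser ones were kept more (Spearman 0.736, permutation p of 0.00018, adjusted 0.00036). The Pearson correlation was 0.596 (permutation p of 0.00521, adjusted 0.00521). Without the 2 densities farthest from the median the correlations were 0.719 and 0.611. These p-values take chromosomes as units within 1 pair of libraries and do not cover differences between libraries. The 21 autosomes held 2.77 to 13.9 genes per Mb and chromosome 19 held 23.7, so a loss at its density was not tested. Within their range, a loss from gene-dense chromosomes in general is argued against. Nor were only weak regions affected, since in the strongest WT decile 85.2% (82.2 to 87.8%) of 640 chromosome 19 regions were kept against 98.3% (97.8 to 98.8%) elsewhere on autosomes, and among 14577 shared regions, ranked anew within that common set, those of chromosome 19 stood a median 10.7 points lower in 195C>G (others -3.15 to 0.960), or 9.12 points against regions of like WT rank (others -2.27 to 1.63). Whether clone, copy number, the variant or library preparation lies behind it was not tested.

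Chromosome 19 also held a larger share of the WT list than of the 195C>G list, and which library departs could not be decided. The 1578 K562 regions of chromosome 19 were found in 195C>G at -0.519 points from regions matched on order and promoter status (other autosomes -10.2 to 10.1), and in WT at 13.2 points (others -17.6 to 11.2). That WT value exceeded the next, chromosome 13, by 1.97 points with a counting standard error of 3.70, and the WT and 195C>G values move together on many other autosomes, such as 11.2 and 10.1 on chromosome 13, so a value near 0 is no neutral point. By share of each list, 195C>G (7.02%) lay below and WT (10.9%) above K562 (9.11%) and BCL11A (9.30%). K562 is also a line with its own chromosome copies, so biological and technical sources stay open.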
